A study of Homo sapiens with 12 samples.

How the data were processed

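The values used were raw gene counts, one column per library, taken as deposited; the authors made them by aligning the reads with HISAT2 and counting them per gene with featureCounts, per the labels, after a quality check with FastQC. The labels also name limma and give no version for any of these tools, and the genome build and annotation of the table were not given in the sources used here. Per the labels, RNA was isolated with RNeasy kits and columns that remove genomic DNA, and cDNA was made with the SMART-Seq v4 kit, which primes on poly(A) and does not mark strand. Libraries were sequenced as 75 bp paired reads on an Illumina HiSeq instrument, about 50 M reads per sample.

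The table held 22997 gene IDs, of which 20579 matched GENCODE 29 with their version and 22810 without it, and a symbol was found for 22633. XIST, TSIX and Y-linked genes, 29 in all, were left out after the library totals had been summed, which left 22968. No gene of the mitochondrial genome was in the table, so the planned share of mitochondrial protein gene counts could not be computed and these genes were not analysed here. Gene types and symbols came from GENCODE 29 and a gene names table, and no coordinate of the study's own genome was used. The lowest sum over the 12 libraries was 38 counts, so the table had lost genes with few counts before it was deposited.

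The analysis ran in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0 and in Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9. Genes were kept by filterByExpr on the groups, which left 19740, and library sizes were scaled with TMM factors. The test was edgeR's robust quasi-likelihood F test of hypoxia against normoxia over all 12 libraries, without a block, and genes were called at a Benjamini-Hochberg adjusted p under 0.05 with no floor on the fold. This test, the gene lists and the alternatives were fixed before the data were examined. CPM values are TMM-normalised, log2 values carry a prior count of 2, and the number after ± is the SD for a CPM or share and the standard error for a log2 fold change.

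Lists were tested with limma's camera, which asks whether members rank higher or lower than other genes, with a preset inter-gene correlation of 0.01, and adjusted over the 28 lists that had at least 3 measured members. With the preset value 9 lists were called without the block and 9 with it; with the correlation estimated from the data these became 2 and 0. The fry test, which asks whether the members as a set moved in one direction whatever other genes did, was run beside it. Without the block fry did not pass the ribosomal protein, cholesterol synthesis and stem cell lists that camera called (fry adjusted p = 0.184, 0.139 and 0.217). It passed the Notch pathway components, not called by camera, in both fits (0.00115, and 0.00288 with the block). With the block fry also passed lists camera did not call, such as the mast cell, basophil and eosinophil list (0.00661 against 0.131 by camera). Others were the erythroid, granulocyte and monocyte progenitor, NF-kappaB, and mature monocyte and neutrophil lists (0.00701, 0.00924, 0.0185 and 0.0306).

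The replicate numbers 1 to 6 occur once in each group, and the labels' protocol speaks of 6 donors without saying which library came from which, so the pairing was an alternative and not the test. After group means were removed, same-numbered libraries correlated at 0.581 to 0.648 and others at −0.264 to 0.008, and 12 of 12 libraries correlated best with the one of their own number. Within groups no library was a copy of another (chi-square per degree of freedom of 14.4 to 42.5 over 30 pairs). The common biological coefficient of variation was 15.4% without the block and 6.23% with it. The test without the block thus left the spread shared by same-numbered libraries in its error. A gene that did not pass without the block was therefore not shown to be unchanged. The first principal components held 17.9% and 17.3% of the variance.

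In a self-test with planted changes, the fit without the block recovered 7.5% of genes changed 1.2-fold, 44.8% of those changed 1.5-fold and 63.6% of those changed 2-fold, with 0 false calls among 77. The fit with the block recovered 52.2%, 73.1% and 93.9%, with 10 false calls among 156. The simulated counts carried differences between replicate numbers and the spread estimated with the block, and 200 of 19740 genes were changed. The self-test therefore favoured the fit with the block and is no independent comparison of the 2 fits. None of 20 random lists was called and the list with planted rises was.

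Genes named in the text follow a rule. In each direction and each fit it took the 10 called genes with the largest log2 fold change, a mean log2 CPM of at least 2 and a symbol that is not a clone or LOC name. It also took up to 4 called members with the smallest p from each list with any call, and 15 genes named in advance whatever their values, of which CA9 and DTX1 were under the filter. From this set the text names a part. MYC, RFNG, the histone genes and genes overlapping 18S ribosomal RNA copies were added after the results were seen. Genes that can carry a donor's genotype, such as HLA genes, were not named.

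Library measures were compared by a two-sided exact permutation test on the difference of means and by sign flips over the 6 same-numbered pairs. Alternatives were DESeq2, limma-voom and limma-voom with the replicate number as a random effect, RLE factors, library totals alone, no filter and a stricter one, each library or replicate left out, and the replicate block. Thinning to the smallest library total and a fit with the log2 share of 18S-overlapping genes beside the block were added after results were seen.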

Results

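The series measured gene expression in human CD34+ blood stem and progenitor cells that had been mobilised from the marrow of healthy donors with G-CSF, a growth factor that releases them into the circulation. The cells were cultured for 24 hours on vessels coated with Delta1ext-IgG, an immobilised form of the Notch ligand Delta1 fused to an antibody tail, with stem cell factor, FLT3 ligand and thrombopoietin in the medium. Of the 12 bulk RNA-seq libraries, 6 came from cultures under normoxia and 6 from cultures under hypoxia, and each group carries the replicate numbers 1 to 6. The coating was made at 10 µg/mL for normoxia and at 5 µg/mL for hypoxia, so oxygen and ligand density changed together in all 12 libraries and the comparison is one of culture conditions. The libraries held between 20.9 and 42.8 M counts (M for mega), with a mean of 26.1 M ± 4.03 in normoxia and 32.5 M ± 7.20 in hypoxia (SD, n = 6 each; two-sided exact permutation p = 0.0909).

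The comparison asks which genes CD34+ cells express differently when Notch ligand culture is moved from normoxia to hypoxia. Genes that hypoxia-inducible factors (HIF) activate and genes of glycolysis rose together. BNIP3, a mitophagy receptor, went from 11.3 ± 0.672 to 84.2 ± 24.7 CPM (counts scaled to a common library size; mean ± SD, n = 6 per group), a 7.49-fold rise (adjusted p = 1.62e-05). LDHA, which turns pyruvate into lactate, went from 475 ± 39.5 to 1048 ± 154 CPM, a 2.21-fold rise (adjusted p = 2.20e-05). On the other side, HDC, the enzyme that makes histamine, fell from 100 ± 22.5 to 52.8 ± 16.3 CPM (log2 fold change −0.93 ± 0.22 SE, adjusted p = 0.0281), a call that ended in 4 of 6 runs without 1 replicate number and in 6 of 12 without 1 library; with the replicate block it was −0.95 ± 0.07 (adjusted p = 7.69e-06). The golgin gene GOLGA8B fell from 16.7 ± 2.24 to 7.12 ± 1.17 CPM (−1.23 ± 0.12, adjusted p = 4.48e-05). Each of these 4 genes changed in the same direction in 6 of 6 same-numbered pairs.

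**Figure D1:**
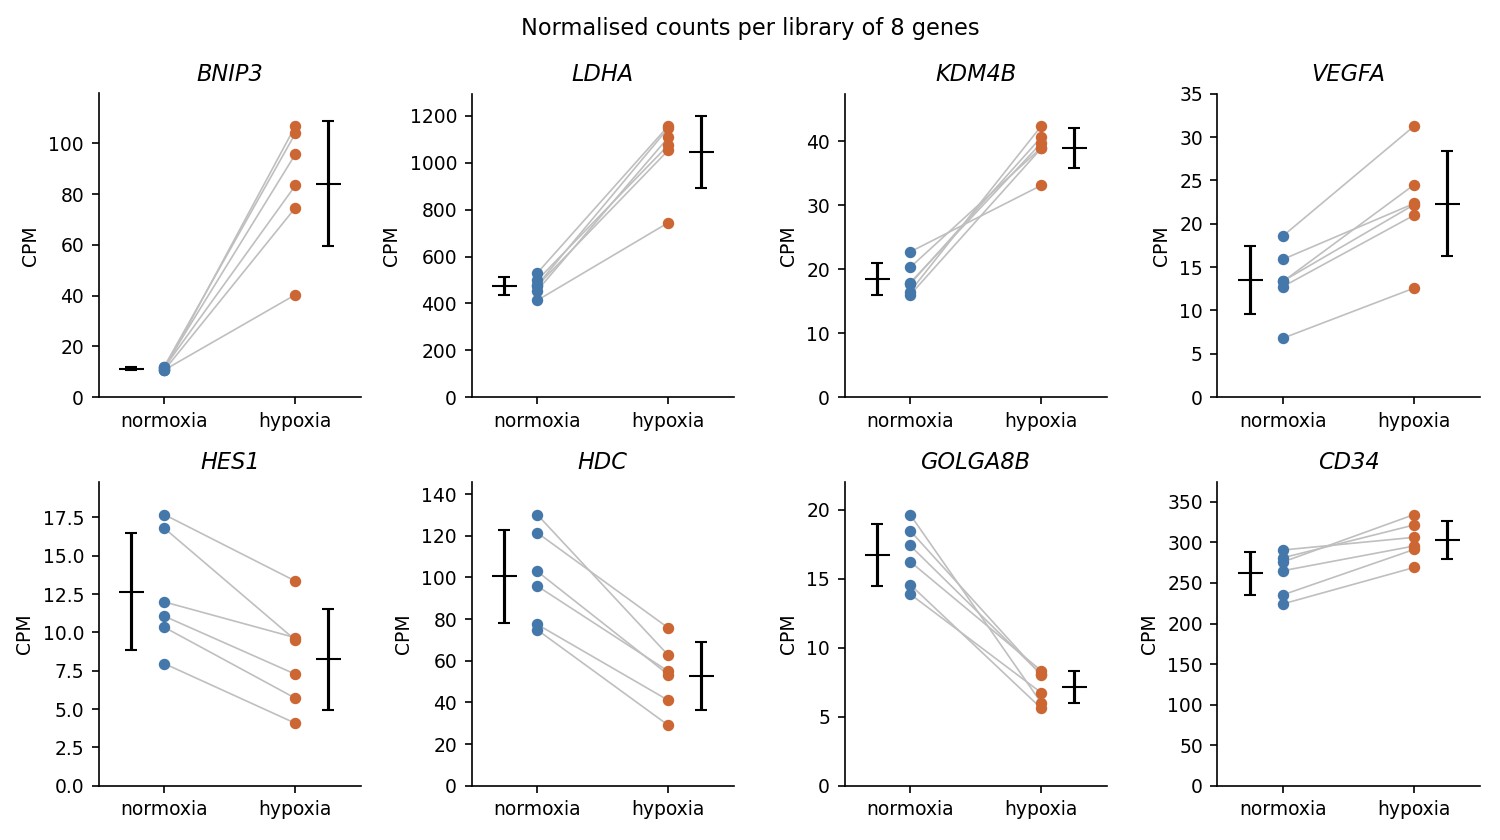
Normalised CPM (vertical axes, linear from 0) of 8 genes in the 6 normoxia (blue) and 6 hypoxia (orange) libraries, with grey lines joining libraries of the same replicate number and black bars giving the mean ± SD. BNIP3, LDHA and KDM4B show no overlap between the groups, whereas VEGFA, HES1 and CD34 overlap but shift in one direction in all 6 pairs.

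Of 19740 genes tested with edgeR's quasi-likelihood test, 613 were higher and 569 lower in hypoxia at a Benjamini-Hochberg adjusted p under 0.05. Most changes were small. Of the called genes, 68 of the higher and 24 of the lower genes changed by more than 2-fold. The median absolute log2 fold change was 0.34 among the higher and 0.38 among the lower genes. With the replicate number as a block, which compares hypoxia and normoxia within same-numbered pairs, 2481 genes were higher and 2106 lower. Of the calls without the block, 612 of the 613 and 567 of the 569 were called again in the same direction. Scaling by library totals alone, in place of TMM factors, called 343 higher and 1004 lower genes, so that 25.5% of its calls were higher against 51.9% with TMM. Besides that of HDC, the calls without the block of ARNT, BAG3, CKAP2, MAP1LC3B, NDUFB4, PSEN1, RPL3, RPS3, SREBF2 and TOP2A ended in 5 of 6 runs without 1 replicate number, those of AEN, HERC2P2, SQLE and TM7SF2 in 4, and those of JUN, TET1 and TMEM45A in 2; with the block each of these genes passed.

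**Figure D2:**
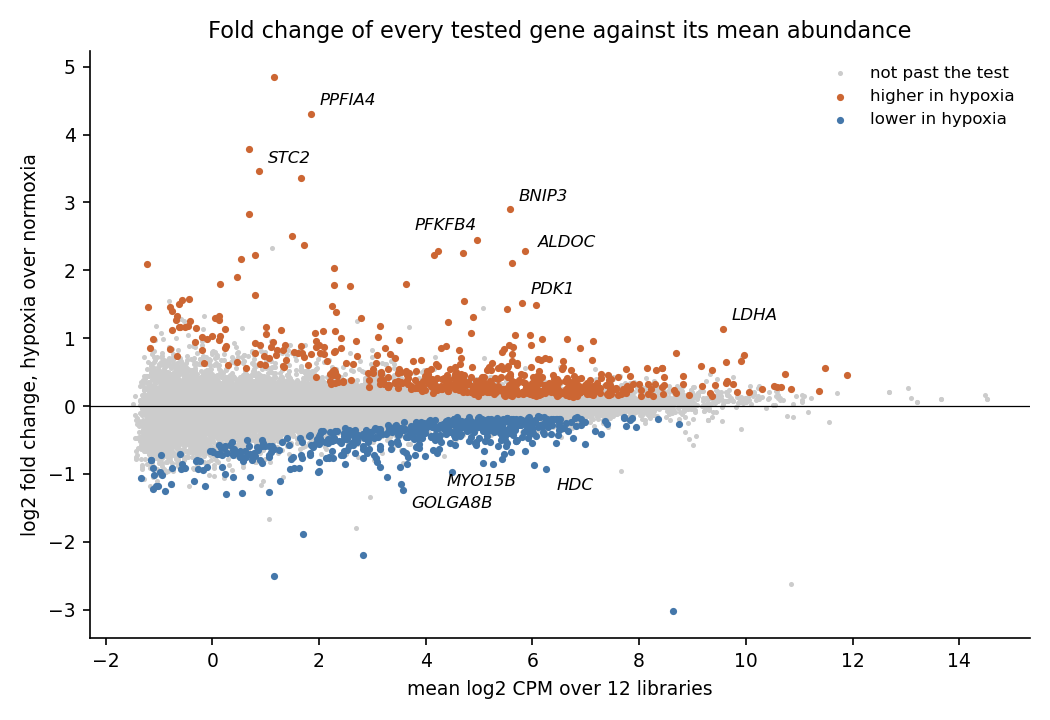
Log2 fold change, hypoxia over normoxia, of each of the 19740 tested genes (vertical axis) against its mean log2 CPM over the 12 libraries (horizontal axis), with 613 higher genes in orange, 569 lower genes in blue and the rest in grey. BNIP3 (2.90), PFKFB4 (2.44) and ALDOC (2.28) have the largest rises among genes with a symbol and a mean log2 CPM of at least 2. The blue point lowest on the plot is ENSG00000280614 (−3.02), which overlaps an 18S ribosomal RNA copy.

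Among 32 measured HIF target genes, 23 rose and none fell, and 28 rose when p was adjusted over the list alone. The median log2 fold change was 0.87 (camera adjusted p = 6.10e-31; adjusted p = 0.0499 with an estimated correlation, and 0.349 with that and the block). PPFIA4, a liprin scaffold gene, rose 19.8-fold from a low level of 0.316 ± 0.143 CPM to 6.47 ± 2.94. STC2, which encodes a secreted glycoprotein, rose 11.0-fold from 0.274 ± 0.175 to 3.08 ± 1.36. DDIT4, an inhibitor of mTORC1 signalling, rose 4.77-fold (adjusted p = 2.26e-05). P4HA1, a collagen prolyl hydroxylase, rose 2.81-fold (adjusted p = 1.57e-05), and BHLHE40, a transcriptional repressor, rose 1.63-fold (adjusted p = 7.44e-05). TMEM45A (2.03 ± 0.41 on the log2 scale) and VLDLR, a lipoprotein receptor (1.77 ± 0.24), also rose. VEGFA, the angiogenic growth factor, was at 13.5 ± 3.93 and 22.3 ± 6.02 CPM and did not pass without the block (log2 fold change 0.73 ± 0.23, adjusted p = 0.0870), but did with it (0.73 ± 0.06, adjusted p = 1.93e-07). CA9 lay under the filter on low counts.

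Of 25 glycolysis genes, 21 rose and none fell, and 23 rose when adjusted over the list alone. The median log2 fold change was 0.67 (camera adjusted p = 6.38e-29; adjusted p = 0.0499 with an estimated correlation, and 0.349 with that and the block). PFKFB4, which raises the main activator of phosphofructokinase, rose 5.45-fold, the aldolase gene ALDOC rose 4.87-fold and the lactate exporter SLC16A3 rose 4.32-fold (adjusted p = 0.000507, 0.000128 and 3.05e-05). The pyruvate dehydrogenase kinase gene PDK1 rose from 28.7 ± 5.85 to 82.6 ± 12.6 CPM (2.88-fold, adjusted p = 4.69e-05) and the glucose transporter gene SLC2A1 from 40.2 ± 2.74 to 83.4 ± 12.4 CPM (2.08-fold, adjusted p = 2.26e-05). The abundant members ALDOA and GPI rose 1.69-fold and 1.72-fold. The 63 nuclear genes of oxidative phosphorylation had a median log2 fold change of 0.02, and 1 of them rose, NDUFB4 (0.20 ± 0.05, adjusted p = 0.0438), or 0 when adjusted over the list alone, and its call ended in 9 of 12 runs without 1 library. With the block 5 rose and 2 fell. The list was called in neither fit (camera adjusted p = 0.381, and 0.309 with the block).

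Both lists rose less in hypoxia replicate 6. Within same-numbered pairs the median log2 difference of the HIF targets was 0.49 in pair 6 and between 0.73 and 1.15 in pairs 1 to 5, and that of the glycolysis genes was 0.49 in pair 6 and between 0.69 and 0.89 in the others. Library composition also differed between the groups. Genes that overlap copies of the 18S ribosomal RNA gene on chromosome 21 took 0.393% ± 0.112 of counts in normoxia and 0.0610% ± 0.0917 in hypoxia (SD, n = 6 each), a difference of −0.332 percentage points (two-sided exact permutation p = 0.002165, the smallest this test can give). Hypoxia replicate 6 stood at 0.247% against 0.0114% to 0.0398% in the other hypoxia libraries. This measure was chosen after the values were seen. Without replicate 6, 645 genes were higher and 583 lower in hypoxia, whereas without any 1 of replicates 1 to 5 between 296 and 348 were higher and between 272 and 359 lower.

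**Figure D3:**
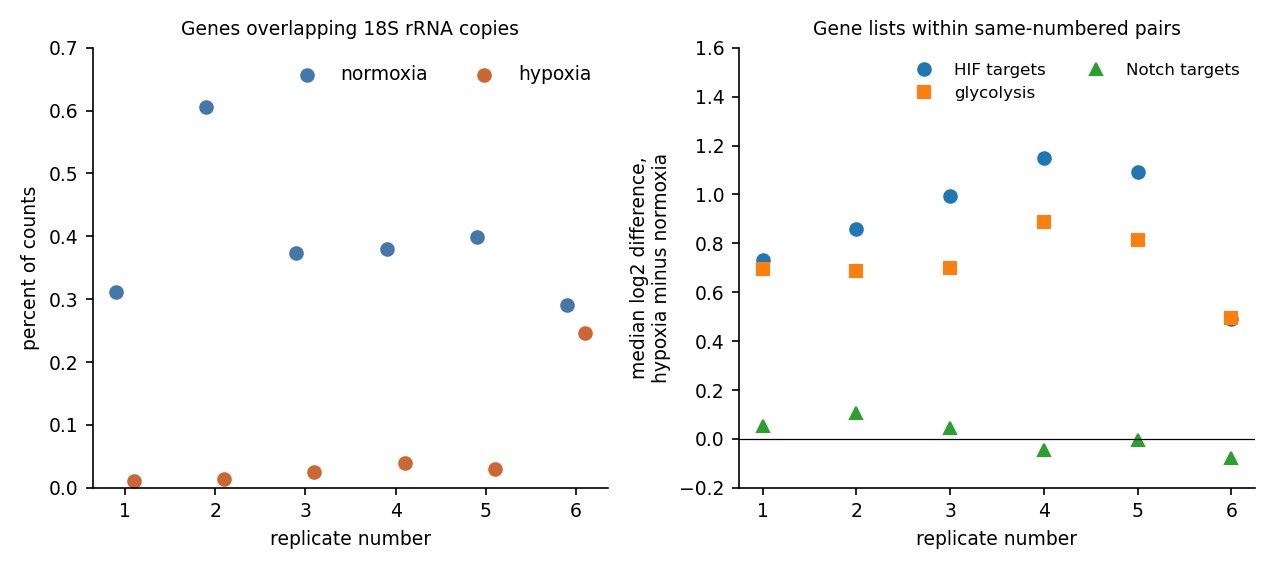
Left, the percentage of each library's counts in genes overlapping 18S ribosomal RNA copies, by replicate number, in normoxia (blue) and hypoxia (orange); right, the median log2 difference, hypoxia minus normoxia, of the HIF target, glycolysis and Notch target lists within each same-numbered pair. Pair 6 has the smallest difference in the left panel (0.292% and 0.247%) and the smallest medians of the HIF target and glycolysis lists (0.49 each).

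Among 12 components of the HIF pathway, 3 rose: the oxygen-sensing prolyl hydroxylases EGLN3 (3.49-fold, adjusted p = 0.00180) and EGLN1 (1.87-fold, adjusted p = 0.000363), and the HIF partner ARNT (1.15-fold, adjusted p = 0.0433). When adjusted over the list alone 3 passed, and with the block 4 rose and 1 fell. The list was called (camera adjusted p = 0.0285) but not with an estimated correlation (adjusted p = 0.180 with an estimated correlation) nor with the replicate block (adjusted p = 0.0845). EGLN3 and EGLN1 are also members of the HIF target list, so this call is not separate from the rise of that list. HIF1A mRNA was at 86.8 ± 2.34 and 92.6 ± 3.33 CPM (log2 fold change 0.09 ± 0.04, adjusted p = 0.165). EPAS1, which encodes HIF-2α, was at 4.18 ± 1.48 and 2.96 ± 0.879 CPM (−0.50 ± 0.25, adjusted p = 0.271; with the block −0.51 ± 0.10, adjusted p = 0.00196).

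Chromatin and RNA demethylases that use oxygen as a substrate shifted upward. Of 20 such genes 7 rose (8 when adjusted over the list alone), with a median log2 fold change of 0.14 (camera adjusted p = 3.42e-06; adjusted p = 0.288 with an estimated correlation). The histone H3K9 demethylases KDM4B (18.5 ± 2.54 to 39.0 ± 3.14 CPM, 2.10-fold), KDM3A (1.86-fold) and KDM4C (1.24-fold) rose, as did the H3K4 demethylase KDM5B (1.31-fold), the 5-methylcytosine dioxygenase TET1 (1.34-fold) and the m6A RNA demethylase ALKBH5 (1.27-fold, adjusted p = 0.000774). With the block, 13 of the 20 rose. KDM4B and KDM3A are also members of the HIF target list.

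The cholesterol synthesis, ribosomal protein, autophagy and immediate early lists were called upward with small medians. Of 22 cholesterol synthesis genes, 4 rose (11 when adjusted over the list alone; 15 over all genes with the block): the LDL receptor gene LDLR (log2 fold change 0.31 ± 0.06), TM7SF2 (0.39 ± 0.09), SQLE (0.26 ± 0.06) and SREBF2, the transcription factor that drives the pathway (0.18 ± 0.05). The median was 0.24 (camera adjusted p = 7.51e-06; adjusted p = 0.653 with an estimated correlation). Of 47 ribosomal protein genes, 3 rose, RPS16 (0.44 ± 0.08), RPL3 (0.30 ± 0.08) and RPS3 (0.25 ± 0.07), 8 did so when adjusted over the list alone and 27 with the block. The median was 0.15 (camera adjusted p = 7.59e-09; adjusted p = 0.654 with an estimated correlation). Their share of counts was 4.17% ± 0.305 in normoxia and 4.49% ± 0.253 in hypoxia (SD, n = 6 each; two-sided exact permutation p = 0.0736; higher in 6 of 6 pairs, sign-flip exact p = 0.0313, the smallest that 6 pairs can give). Of 13 autophagy and mitophagy genes, BNIP3, its paralog BNIP3L (1.94-fold), MAP1LC3B and ATG7 rose (4, likewise 4 when adjusted over the list alone), but the median of the list was 0.02. Its call (camera adjusted p = 0.0256) was lost with estimated correlations (adjusted p = 0.392 with an estimated correlation) and with the block (adjusted p = 0.170). BNIP3 and BNIP3L are also members of the HIF target list. Of 10 immediate early genes, JUN (0.99 ± 0.23) and IER2 (0.27 ± 0.05) rose (2, and 4 when adjusted over the list alone), and EGR1 did with the block (0.85 ± 0.18, adjusted p = 0.00558). JUN was at a low level, 0.568 ± 0.142 CPM in normoxia and 1.14 ± 0.296 CPM in hypoxia. The call of the list (camera adjusted p = 0.0285) was lost with an estimated correlation (adjusted p = 0.354 with an estimated correlation), and it was kept in 28 of 38 alternative settings.

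**Figure D4:**
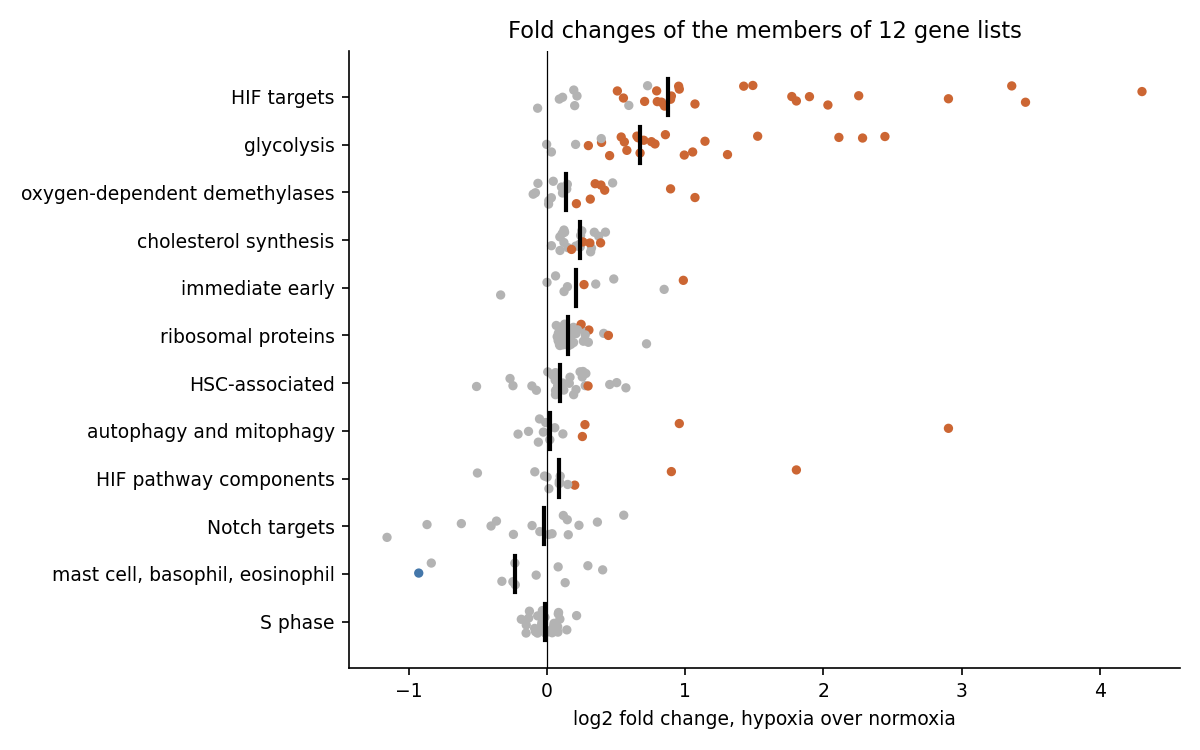
Log2 fold change, hypoxia over normoxia (horizontal axis), of each measured member of 12 gene lists, one point per gene, coloured orange where higher and blue where lower at adjusted p under 0.05 and grey otherwise, with a black bar at the list's median; vertical scatter within a row has no meaning. The medians are 0.87 for HIF targets and 0.67 for glycolysis and lie between −0.23 and 0.24 for the other 10 lists.

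Genes associated with haematopoietic stem cells moved in both directions. Among 30, 1 passed the test without the block, the stem cell factor receptor gene KIT (126 ± 7.62 to 155 ± 10.5 CPM, 1.23-fold, adjusted p = 0.00542), and 1 when adjusted over the list alone. The list was called (median log2 fold change 0.10, camera adjusted p = 0.0285; adjusted p = 0.654 with an estimated correlation). With the block 11 rose and 2 fell. CD34 itself was at 262 ± 26.6 and 303 ± 23.2 CPM (0.21 ± 0.07, adjusted p = 0.103; with the block 0.21 ± 0.04, adjusted p = 0.000901). PROCR, which encodes the surface marker EPCR (0.46 ± 0.10, adjusted p = 0.00272), HOPX (0.51 ± 0.07, adjusted p = 0.000288) and GATA2 (0.24 ± 0.04, adjusted p = 0.000282) rose with the block, while the stem cell transcription factor gene HLF fell (−0.27 ± 0.05, adjusted p = 0.000577). None of CD34, PROCR, HOPX, GATA2 and HLF passed without it (adjusted p = 0.103, 0.213, 0.0852, 0.183 and 0.309). MECOM passed in neither fit (−0.11 ± 0.13, adjusted p = 0.698; with the block −0.11 ± 0.05, adjusted p = 0.115).

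Notch target genes, which bear on the ligand the cells were cultured on, showed no common direction. None of 16 measured targets passed without the block or when adjusted over the list alone, the median log2 fold change was −0.02 and the list was not called (camera adjusted p = 0.662). At an unadjusted p under 0.05 in edgeR 4 were lower and 0 higher, and DESeq2 and limma-voom called 0. The Notch effector HES1 was at 12.6 ± 3.82 CPM in normoxia and 8.26 ± 3.30 CPM in hypoxia (log2 fold change −0.62 ± 0.27, adjusted p = 0.213). Within pairs it fell in 6 of 6 (with the block −0.63 ± 0.08, adjusted p = 4.57e-05). With the block HES4 (−1.03 ± 0.30, adjusted p = 0.0213, below 1 CPM in both groups) and TCF7 (−0.38 ± 0.11, adjusted p = 0.0210) also fell, and CCND1 (0.62 ± 0.12, adjusted p = 0.000992) and MYC (0.12 ± 0.04, adjusted p = 0.0305) rose; MYC was chosen after its values were seen. NRARP, a feedback inhibitor induced by Notch, passed in neither fit (0.15 ± 0.13, adjusted p = 0.553; with the block 0.15 ± 0.07, adjusted p = 0.129), and DTX1 lay under the filter on low counts. Among 27 Notch pathway components 1 rose, the presenilin gene PSEN1 (0.20 ± 0.06, adjusted p = 0.0451; the call ended in 10 of 12 runs without 1 library), or 2 when adjusted over the list alone (camera adjusted p = 0.192). With the block 7 rose and 1 fell (camera adjusted p = 0.173). The ligand gene JAG2 (0.89 ± 0.19, a mean below 1 CPM in both groups), the glycosyltransferase gene LFNG (0.29 ± 0.07) and the receptor gene NOTCH2 (0.13 ± 0.04) were among the higher. RFNG, a paralog of LFNG named after its values were seen, was the lower (−0.16 ± 0.05, adjusted p = 0.0325). NOTCH1 did not pass (0.02 ± 0.03, adjusted p = 0.792).

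Markers of the lineages that a CD34+ culture can hold gave few calls without the block. Of 11 mast cell, basophil and eosinophil genes 1 fell, HDC, and 1 fell when adjusted over the list alone (median −0.23, camera adjusted p = 0.416). With the block 6 of them fell, among them MS4A2, the beta chain of the IgE receptor (−0.90 ± 0.11, adjusted p = 0.000133), FCER1A, its alpha chain (−0.31 ± 0.05, adjusted p = 0.000469), and the carboxypeptidase gene CPA3 (−0.23 ± 0.03, adjusted p = 0.000168), while 2 rose. The 2 were the tryptase gene TPSAB1 (0.43 ± 0.07, adjusted p = 0.000181) and CLC (0.14 ± 0.05, adjusted p = 0.0347). Reads of TPSAB1 can be shared with its near-identical paralog TPSB2, which did not pass (0.28 ± 0.19, adjusted p = 0.334). No gene of the erythroid, megakaryocyte and platelet, or granulocyte and monocyte progenitor lists passed without the block in edgeR, DESeq2 or limma-voom. At an unadjusted p under 0.05 in edgeR, 1, 2 and 0 of their genes differed. With it, 9 of 16 megakaryocyte and platelet genes rose and 1 fell (camera adjusted p = 0.0200; adjusted p = 0.349 with an estimated correlation), including the integrin gene ITGB3 (0.63 ± 0.07), GP1BB (0.46 ± 0.07) and CMTM5 (0.92 ± 0.15). Of 13 granulocyte and monocyte progenitor genes, 5 fell and 2 rose with the block (camera adjusted p = 0.196), the granule genes PRTN3 (−0.45 ± 0.05) and RNASE2 (−0.29 ± 0.05) among those that fell. Of 14 erythroid genes, 3 rose and 1 fell with the block (camera adjusted p = 0.117). The transferrin receptor gene TFRC (0.41 ± 0.04) and HBD (0.62 ± 0.13) were among the higher and CA1 was the lower (−0.71 ± 0.14). The mature monocyte and neutrophil, dendritic, B-lymphoid and T and NK lists were called in neither fit (camera adjusted p = 0.765, 0.416, 0.873 and 0.424 without the block), and with the block at most 1 gene of each rose and at most 1 fell.

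Cell cycle and stress lists gave few calls without the block. None of 33 S-phase genes passed in edgeR without the block (median −0.01, camera adjusted p = 0.861), although 4 did at an unadjusted p under 0.05 and 1 was lower in DESeq2; with the block 2 rose and 3 fell. Of 39 G2/M genes TOP2A (0.15 ± 0.04, adjusted p = 0.0479) and CKAP2 (0.20 ± 0.05, adjusted p = 0.0205) rose, or 1 gene when adjusted over the list alone (camera adjusted p = 0.0645), and the call of TOP2A ended in 11 of 12 runs without 1 library. With the block 12 rose and 3 fell (camera adjusted p = 0.0364; adjusted p = 0.377 with an estimated correlation). MKI67, the proliferation marker, passed with the block (0.30 ± 0.04, adjusted p = 0.000124) but not without it (adjusted p = 0.0791). Single genes passed in the p53 list (AEN, −0.22 ± 0.06), the oxidative stress list (FTH1, the ferritin heavy chain gene, 0.40 ± 0.06), the heat shock list (BAG3, 0.38 ± 0.10) and the amino acid and unfolded protein response list (VLDLR). None of these lists was called (camera adjusted p = 0.542, 0.381, 0.416 and 0.533). Adjusted over the list alone, 2 of 18 p53 genes rose and 3 fell, and with the block 3 rose and 6 fell. With the block, 2 of 11 heat shock genes rose, 3 of 18 genes of the amino acid and unfolded protein response list rose and 4 fell, and 5 of 14 oxidative stress genes rose and 2 fell. The serine synthesis gene PSAT1 (−0.51 ± 0.07) and the cystine transporter gene SLC7A11 (−0.58 ± 0.14) were among the lower, and PHGDH, another serine synthesis gene, was among the higher (0.15 ± 0.03, adjusted p = 0.00319). The interferon and NF-kappaB lists were called in neither fit (camera adjusted p = 0.873 and 0.173 without the block); with the block 4 interferon genes rose and 2 fell, and 1 NF-kappaB gene rose.

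The other genes with the largest changes by the naming rule belonged to no list. SDK2, a cell adhesion gene, rose 2.93-fold (adjusted p = 0.00266). DDIT4-AS1 rose 4.69-fold, but it lies antisense to DDIT4 and the library kit does not mark strand, so its reads and those of DDIT4 cannot be told apart. Besides HDC and GOLGA8B, the largest falls were in HERC2P2 (−0.97 ± 0.23), NSUN5P1 (−0.90 ± 0.13), SAPCD1 (−0.90 ± 0.09), MYO15B (−0.87 ± 0.08), the read-through locus STAG3L5P-PVRIG2P-PILRB (−0.85 ± 0.13), AMY2B (−0.85 ± 0.12), PGGHG (−0.85 ± 0.14) and PILRB (−0.84 ± 0.12), each lower in 6 of 6 pairs. GOLGA8B, HERC2P2, NSUN5P1 and AMY2B have close copies in the genome and the read-through locus overlaps PILRB, so their counts are uncertain as to the copy they come from. Sense-intronic genes, which lie inside introns, took 0.0603% ± 0.00295 of counts in normoxia and 0.0546% ± 0.00277 in hypoxia (SD, n = 6 each; two-sided exact permutation p = 0.0152), a measure chosen after the values were seen. The block added ACY3 (−1.26 ± 0.14, adjusted p = 7.77e-05; adjusted p = 0.0823 without it) and MTATP6P1 (−0.84 ± 0.18, adjusted p = 0.0157; adjusted p = 0.0848 without it), a nuclear copy of a mitochondrial gene whose reads can be shared with its source.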

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

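In this part the tests on HES1, the measures of 18S ribosomal RNA overlap, sense-intronic and snoRNA counts, and thinning were chosen after results had been seen. In each group of 6 libraries the highest or lowest library was compared with the rest by its gap to the nearest other library as a share of the group's range, and 19 of 210 such groups exceeded the critical value for 6 libraries. Chance alone gives about 1 in 20, which would be 10.5 groups. Of the 19, 8 concerned hypoxia replicate 6.

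In hypoxia, replicate 6 was lowest for LDHA (744 CPM against 1054 to 1157; gap share 0.751), ALDOA (966 against 1266 to 1346; 0.789), GPI (395 against 518 to 587; 0.642), KDM4B (33.1 against 38.9 to 42.4; 0.6251) and NDUFB4 (61.6 against 66.8 to 69.6; 0.646). It was highest for MTATP6P1 (11.7 against 3.75 to 5.59; 0.768), for NRARP (10.8 against 6.43 to 7.52; 0.747) and for the share of counts in genes overlapping 18S copies (0.247% against 0.0114% to 0.0398%; 0.879). Normoxia replicate 6 was also highest for NRARP (8.67 against 6.11 to 6.72; 0.764). Normoxia replicate 2 had the highest share of 18S-overlapping counts in its group (0.605% against 0.292% to 0.398%; 0.660). Replicate 3 was highest for CPA3 in normoxia (165 against 69.8 to 102; 0.659) and in hypoxia (141 against 57.4 to 86.4; 0.654), and in normoxia for HBD (126 against 12.6 to 50.5; 0.667), CA1 (12.4 against 1.70 to 5.16; 0.677) and SLC7A11 (9.56 against 6.79 to 7.75; 0.652). Normoxia replicate 1 was lowest for PPFIA4 (0.0437 against 0.318 to 0.434; 0.703) and normoxia replicate 5 for FTH1 (137 against 153 to 161; 0.649). Hypoxia replicate 5 was highest for PROCR (5.92 against 2.96 to 3.79; 0.720) and hypoxia replicate 4 lowest for JAG2 (0.612 against 0.894 to 1.05; 0.645).

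Chance is an unlikely source of the number of called genes, although 100 and 32 splits are too few to exclude it. Without the block, 1 of 100 drawn splits of the 12 libraries into 6 and 6 called as many genes, the real one with 1182, and the highest other split, which parted 4 same-numbered pairs, called 307. With the block, 1 of the 32 splits that part all 6 pairs called as many, the real one with 4587, and the highest other, with 1 pair swapped, called 5. A difference in depth was argued against as the whole source, since 82.1% of the called genes were called again with the same sign after thinning to the smallest library total.

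The first pattern weighed is the fall of mast cell and basophil genes, of which 6 fell with the block. The list covers mast cells, basophils and eosinophils. An equally lower share of all these cells in the hypoxia cultures would lower the members by about the same amount. However, 30.0% of 10 members at a mean log2 CPM of at least 2 had log2 fold changes below −0.3. That share alone cannot tell an equal small fall from an unequal one. EPX (−0.28), MS4A3 (−0.26) and CPA3 (−0.23) also fell but lay above the cutoff, while 2 members of the list rose. The members ranged from −0.95 (HDC) to 0.43 (TPSAB1), more than their standard errors allow (Cochran Q = 342 on 9 degrees of freedom, p = 3.15e-68, a test on counts across genes and not on permuted libraries, so not exact). That argues against an equal shift in all these cells as the whole source. A lower share of only some of these cells would also leave the members unequal, so the test cannot exclude it. Lower HDC and MS4A2 expression within cells, and a change in the kind of mast cell or basophil precursor, stay open and were not tested.

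The second pattern is a small downward shift of genes with many intron-retaining transcripts. The 516 protein-coding genes whose transcripts are mostly of the retained-intron type had a median log2 fold change of −0.038 relative to matched protein-coding genes (95% interval −0.055 to −0.029). Intervals for these gene sets come from resampling genes, so they do not measure the spread between cultures. With the block 20.3% of the 516 fell and 12.4% rose, against 10.8% and 15.4% of other protein-coding genes. A lower share of unspliced or genomic sequence in the hypoxia libraries predicts that sense-intronic genes fall as well, and they did, with a relative median of −0.193 (−0.282 to −0.139). Their fall does not single out such sequence, since some other non-coding types also fell. With the block 12 of 54 snRNA genes were lower and 0 higher, and 88 of 769 lincRNA genes were lower and 31 higher. Processed pseudogenes went the other way (82 higher and 22 lower), and the 2185 antisense genes were balanced (152 higher and 151 lower). Depth was argued against for the retained-intron genes, since their relative median after thinning was 89.6% of that at full depth. Unspliced RNA that the cells held and genomic sequence carried over in preparation cannot be separated by these values, and a change of splicing under hypoxia was not tested.

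The third pattern is the fall of HES1 with the block (log2 fold change −0.63). A common fall of the whole Notch target list was argued against. The 15 other members had a median of 0.015 (range −1.03 to 0.62), above 0.5 times the change of HES1 (−0.313). However, 4 of them lay below that value, HES4 (−1.03) among them. The 95% interval of NRARP, 0.015 to 0.288, lay above −0.313 as well. Lower Notch signalling that reached only some of the targets cannot be judged from the median of the list and stays open. Lower ligand density and lower oxygen cannot be told apart as the source, since they part in 0 of the 12 libraries. Regulation of HES1 by hypoxia through a path other than Notch is a hypothesis that was not tested.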

How the results depend on the processing

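Thinning and the fit with the 18S share were chosen after results had been seen; the planned share of mitochondrial protein gene counts was not run. Against 613 genes higher and 569 lower, the replicate block called 2481 and 2106, limma-voom with the block as a random effect 2182 and 2045, DESeq2 995 and 868, DESeq2 with the block 1816 and 1362, library totals alone 343 and 1004, and thinning with the replicate block 2265 and 1850. The block removes the spread between replicate numbers, and the median log2 fold change of all genes was −0.062 with library totals alone against 0.002 with TMM; for the other settings the cause was not tested. limma-voom (619 and 592), RLE factors (612 and 575), no filter (602 and 538), a stricter filter (600 and 622) and thinning without the block (529 and 504) stayed within 1.5 times. With the 18S share beside the replicate block, 31 were higher and 11 lower. The median standard error of the log2 fold changes was 0.153 there against 0.0655 with the block alone, and the median of the HIF target list was 0.567. BNIP3 lost its call, going from 2.85 ± 0.19 with the block (SE, adjusted p = 0.000324) to 2.18 ± 0.33 (adjusted p = 0.118). LDHA stayed past the threshold, at 1.13 ± 0.05 with the block and 0.94 ± 0.11 with the 18S share (adjusted p = 0.00449). The 18S share was lower in hypoxia in 6 of 6 pairs and close between the groups in pair 6 alone (0.292% and 0.247%). Beside the block it therefore ran largely with the group, and this fit cannot part the 18S share from the culture conditions. No gene called in the unpaired fit was called in the opposite direction in any setting.

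Without 1 replicate number, 296 to 645 genes were higher and 272 to 583 lower; without 1 library, 401 to 795 and 395 to 722, the lowest of the higher counts without hypoxia replicate 4 and the highest counts without hypoxia replicate 6; with the replicate block and without 1 number, 1932 to 2091 and 1582 to 1828. Of 28 lists, 9 were called. Other settings with the preset correlation called 8 to 12, runs without 1 replicate number 5 to 10 (5 without replicate 4), without 1 library 8 to 10 and with the block 7 to 10, whereas an estimated correlation left 2, and 0 with the replicate block. HIF targets and glycolysis were called in 37 of 38 alternative settings each, cholesterol synthesis and ribosomal proteins in 36, oxygen-dependent demethylases in 35, stem cell genes in 30, immediate early genes in 28, autophagy in 26 and HIF pathway components in 23.

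Of 97 named genes, 61 kept their side of the threshold with the replicate block and 36 passed it newly. The 18S share beside the replicate block took 43 under the threshold and turned the sign of 2, library totals alone took 12 under it and turned 1, and RLE factors changed 0 of 97. NOTCH1, near 0 throughout, changed sign with library totals alone (−0.055), thinning (0.000), the 18S share (−0.005) and in leave-outs, where it ran from −0.062 to 0.064 without 1 library and from −0.009 to 0.027 without 1 replicate number (−0.009 to 0.031 with the block). PSEN1 changed sign with the 18S share beside the replicate block (−0.013). HES1 ranged from −0.807 to −0.291 over 36 settings and passed in 10; VEGFA passed in 13 and HDC in 26 of 36. Total counts differed by 4.93 to 8.95 M without 1 replicate number (exact permutation p = 0.0397 without replicate 6) and the ribosomal protein share by 0.260 to 0.363 points (exact permutation p = 0.0476 without replicate 1); over pairs, with the replicate block, its difference of 0.320 points passed (sign-flip exact p = 0.0313). Apart from the changes given here and in the report, the block changed no call of a library measure.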

Other observations

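The gene family and gene type comparisons below were chosen after the results had been seen. The Fisher tests treat genes as independent, so their p is too small where members of a family move together. Histone genes rose more often than other protein-coding genes. Of 69 measured, 14 rose and 0 fell without the block, 20.3% against 3.7% of 13638 other genes (Fisher exact test over 86 symbol families, adjusted p = 3.47e-05), and with the block 42 rose and 1 fell (60.9% against 15.1%, adjusted p = 1.02e-15). The linker histone gene H1-0, which accumulates in cells that have stopped dividing, rose from 36.2 ± 7.78 to 61.6 ± 11.3 CPM (mean ± SD, n = 6; edgeR adjusted p = 0.0134), H1-3 from 453 ± 65.6 to 684 ± 98.7 (edgeR adjusted p = 0.00532) and H3C11 from 134 ± 10.0 to 178 ± 14.0 (edgeR adjusted p = 0.00135). H2AZ1, a variant histone gene, was the 1 that fell with the block (log2 fold change −0.25 ± 0.05 SE). The median log2 difference of the family was 0.22, 0.05, −0.01, 0.48, 0.53 and 0.33 in pairs 1 to 6, and the S-phase list had a median of −0.01. Many replication-dependent histone mRNAs lack a poly(A) tail and the kit primes on poly(A), and their near-identical copies can share reads, so the counts of single members are uncertain. The poly(A) limit also bears on the replication-dependent members together. Their rise is therefore one of the RNA that the kit captured and was not shown to be one of total histone mRNA.

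Other symbol families passed with the block alone. The KDM family of histone demethylases (9 of 17 higher, adjusted p = 0.0145) and the RPL family of ribosomal proteins (28 of 50 higher, adjusted p = 2.95e-09) rose more often than other genes, and none of either fell. In the MYO family of myosins 9 of 19 rose (adjusted p = 0.0330) and 4 fell; without the block 1 rose and 3 fell. By camera with the block, the fixed ribosomal protein list was not called with a correlation estimated from the data (correlation 0.631; adjusted p = 0.377 with an estimated correlation), nor was the demethylase list that holds KDM genes (adjusted p = 0.349 with an estimated correlation). With the block the SLC family of transporters fell more often (49 of 249 lower and 27 higher, adjusted p = 0.00349), by Fisher's exact test. Without it 6 of the SLC genes fell and 7 rose. By the same test with the block, the TMEM family rose less often (12 of 170, with 21 lower, adjusted p = 0.0492). Without the block 2 of the TMEM genes rose and 5 fell.

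The number of genes called in each direction is given here by type of gene, with no test between types. With the block, 2095 of 13707 protein-coding genes were higher and 1524 lower. In the same fit 79 of 254 snoRNA genes were lower and 9 higher, 12 of 54 snRNA genes were lower and 0 higher, 88 of 769 lincRNA genes were lower and 31 higher, and 62 of 278 transcribed unprocessed pseudogenes were lower and 12 higher. Of 971 processed pseudogenes, 82 were higher and 22 lower, and of 2185 antisense genes, 152 were higher and 151 lower. Relative to matched protein-coding genes the snoRNA median was −0.235 (95% interval −0.259 to −0.198, from resampling genes and not libraries) and it was below 0 in each of the 6 pairs. The snoRNA share of counts was 1.13% ± 0.306 in normoxia and 0.950% ± 0.214 in hypoxia (SD, n = 6 each; two-sided exact permutation p = 0.264; lower in 6 of 6 pairs, sign-flip exact p = 0.0313).

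Of the genes overlapping 18S copies, ENSG00000280614 fell from 706 ± 264 to 87.1 ± 106 CPM (log2 fold change −3.02 ± 0.73 SE, edgeR adjusted p = 0.0358) and ENSG00000281383 also fell (−2.20, edgeR adjusted p = 0.00565). ENSG00000281181 passed with the block (−3.65, edgeR adjusted p = 0.0358) and not without it (−2.62, edgeR adjusted p = 0.0786). The share of counts in the 100 most abundant genes was 25.9% ± 1.94 in normoxia and 27.0% ± 1.37 in hypoxia (SD, n = 6 each; two-sided exact permutation p = 0.251), and 22894 ± 30.5 and 22908 ± 40.4 genes were detected (exact permutation p = 0.513). The number detected had little room to differ, since the table had lost genes with few counts beforehand and 22968 genes were used.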
